A study of Homo sapiens with 18 samples.

How the data were processed

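Messenger RNA was sequenced from Huh7 cells (8 libraries) and SNU449 cells (6 libraries), and small RNA treated for TRAC-seq from MHCC97H cells (4 libraries). The deposited mRNA values are FPKM, made by the authors with Bowtie2 and HTSeq on GRCh38, with no versions stated and no account of how reads shared between near-identical genes were handled. Gene positions were not used here. The deposited tRNA values are a signal that equals a whole number of reads times 1 factor per library, which held for 100% of values within 0.001, so they are not divided by length although they are named RPKM. The Huh7 table held 18985 genes, of which 26 had symbols turned into dates and 49 a number in place of a name, while 19067 genes were listed for SNU449 and 2222 tRNA features for MHCC97H. The FPKM depth is unknown, and the recovered read counts of the tRNA libraries summed over features to 4692544, 8923006, 10406617 and 19197073 (unheated input, unheated NaBH4, heated input, heated NaBH4). Features of near-identical tRNAs can count the same reads, so these sums can exceed the reads of each library.

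Huh7 genes with a mean of at least 1 FPKM (11495 genes) were fitted on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with 1 mean for each of the 4 groups and empirical Bayes with a trend. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Fixed gene lists with at least 5 tested members (24 of 28) were tested with limma camera at a preset correlation of 0.01, and again with an estimated correlation. The groups, comparisons, tests, lists and first alternatives were fixed before the data were examined. In simulated data every gene was given the same spread, the median over genes of these libraries (SD 0.48). There the fit of all groups recovered 78% of log2 changes of 2, 60% of changes of -2 and 12% of changes of 1 in input. The shares were 78%, 76% and 4% in polysomes, and 28%, 20% and 2% for the ratio. They do not hold for genes with a larger spread, such as HSPA6. The simulation also held no difference between replicates, whereas replicate deviations of the real input groups correlated at 0.71. These shares therefore do not carry over to the real fit.

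SNU449 and MHCC97H had 1 library per group, so differences were computed without tests. SNU449 genes with a mean of at least 1 FPKM (9894 genes) were counted at a difference of at least 1 in log2(FPKM + 1), and list medians were placed among 10000 random lists matched on mean expression in 20 bins. Random lists were drawn gene by gene, so the percentiles take no account of genes that move together or of the spread between libraries. They are not p-values. The polysome comparisons of SNU449 and a comparison of all polysome with all input libraries of Huh7 were chosen after seeing the data. tRNA values were summed over the features of an anticodon with an input signal of at least 10, and the ratio of NaBH4-treated to input signal was taken with a pseudocount of 1. Shares of reads carry 95% Wilson intervals, which cover counting error only and take each read as counted once.

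For Huh7 the named genes were, by a rule set in advance, up to 12 called genes per direction with the largest change, or the 5 with the smallest p per direction where none passed, the study's genes METTL1, WDR4, SNAI1 and SNAI2 (the last under the FPKM minimum), and up to 4 members of a list. For SNU449 they were the 10 largest changes per direction at a mean of at least 5 FPKM, and for MHCC97H the 5 highest and lowest anticodons. Alternatives were a pseudocount of 0.1, a minimum of 5 FPKM or none, median-of-ratios scaling, a replicate block, only the groups compared, no trend, and leaving out each Huh7 library in turn. Later additions were leaving out both replicate 2 polysome libraries, a replicate block, a pseudocount of 0.1, scaling and leaving out each library within the fit of the Huh7 inputs alone, 3′ or 5′ fragments alone and scaling to total reads. No library was relabelled. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest.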

Results

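Gene expression was measured in 18 libraries from 3 human hepatocellular carcinoma cell lines. The labels give the purpose as finding genes whose translation differs with heat and with knockdown of METTL1, the enzyme that places N7-methylguanosine (m7G) on tRNA, and mapping that tRNA mark with and without heat. Heated cells stood at 46 °C for 15 minutes, and culture was at 37 °C. In Huh7 cells, 8 libraries covered unheated and heated cells, each as input mRNA and as polyribosome-associated (polysome) mRNA, with 2 libraries per group. In SNU449 cells, 6 libraries covered cells labelled NC without heat, NC with heat, and a METTL1 short hairpin with heat, each as input and polysome, with 1 library per group. In MHCC97H cells, 4 small RNA libraries came from TRAC-seq, in which demethylation by AlkB is followed by chemical cleavage at m7G with NaBH4, and the AlkB-only library serves as its input. The depth of the mRNA libraries is unknown, since only FPKM values were used, while the read counts of the tRNA libraries summed to 4692544 to 19197073 over features, among which near-identical tRNAs can share reads. Nothing in the labels says that the Huh7 replicates were separate cultures, so their p-values measure only the spread between these samples.

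Heat shock genes were far higher in both heated Huh7 input libraries than in both unheated ones, although no gene passed the planned test. HSPA6, a strictly stress-inducible HSP70, stood at 1.14 and 0.91 FPKM without heat and at 228 and 316 FPKM with heat, a log2 difference of 7.06 (SE 2.25). HSPA1B and HSPA1A, the near-identical inducible HSP70 genes that can share reads, differed by 5.89 and 5.64, and DNAJB1, an HSP40 co-chaperone, by 3.85. Immediate early transcription factors were higher as well, with EGR1 at 4.64, FOS at 3.76, FOSB at 3.46 and JUN at 3.15. Of the integrated stress response genes, ATF3 differed by 3.37 and PPP1R15A, a phosphatase subunit that restores translation, by 1.82.

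With all 4 Huh7 groups sharing 1 spread, limma called 0 of 11495 genes in the heated against unheated inputs, and 71 had an unadjusted p under 0.05. Unchanged genes alone would give a share of about 0.05, so this test was conservative. Its 0 calls do not show that no gene changed. The higher genes with the smallest p were PLCG2 at 2.73, EGR1 at 4.64, TMEM88 at 1.32, ABCB5 at 0.97 and JUN at 3.15. The lower ones were CYP2D7 at -0.997, SMIM11A at -1.39, PET100 at -0.88, GEMIN6 at -1.59 and PSKH1 at -1.01. The spread in that fit took in the polysome libraries, whose replicates went opposite ways for the heat shock genes. It also took in differences between replicates over many genes. All replicate 1 against all replicate 2 libraries, a comparison made after seeing the data, gave 1828 calls. Fitted by themselves, a choice also made in advance, the 4 input libraries gave 19 called genes, all higher with heat. The 12 largest increases among them were those of HSPA6 (adjusted p = 0.000529 in limma), HSPA1B, HSPA1A, EGR1, DNAJB1, CRYAB at 3.82, FOS, FOSB, ATF3, BAG3 at 3.29, DNAJA4 at 3.28 and JUN. With the replicate number as a block, added after seeing the data, the inputs alone gave 532 calls. Replicate deviations of the input groups correlated at 0.71, so the number of calls depends on whether the replicate is in the fit. The labels do not say what a replicate number shares. Leaving out unheated replicate 1 or 2 or heated replicate 1 gave 43, 126 and 46 calls in place of 19, with a lone library assumed to vary like the others. Leaving out both replicate 2 polysome libraries from the fit of all groups gave 18 calls, and both choices were made after seeing the data. With all other libraries in the fit, leaving out the one labelled unheated polysome replicate 1 or 2 gave 2 and 3 calls.

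By fixed gene lists, 37 of 39 heat shock and chaperone genes had a positive input difference (median 1.28), as had 24 of 26 immediate early genes (median 1.22) and 22 of 25 integrated stress response genes (median 0.43). In the fit of all groups, limma called 0 of these members over all genes and 0 when adjusted over the list alone. In the fit of the inputs alone, 9, 5 and 1 members rose, and 24, 16 and 5 rose when adjusted over the list alone. With the preset correlation, limma camera placed 11 of 24 lists apart from other genes, with adjusted p = 1.46e-47, 4.29e-32 and 8.40e-11 for these 3, each with adjusted p = 0.256 with an estimated correlation. Ribosomal protein genes had a negative mean difference in 73 of 79 members (median -0.31, for example RPS27 at -0.68), with camera adjusted p = 4.08e-11 and adjusted p = 0.356 with an estimated correlation. By replicate, their median was 0.0043 in replicate 1 and -0.58 in replicate 2. Nuclear genes of oxidative phosphorylation, such as COX7C at -0.73 and UQCRQ at -0.71, were negative in 31 of 40 (median -0.29), with adjusted p = 2.39e-05 and adjusted p = 0.295 with an estimated correlation. Among mesenchymal genes, 13 of 18 were positive (median 0.18), including FN1 at 1.77 and VIM at 1.05, with adjusted p = 0.00271 and adjusted p = 0.356 with an estimated correlation. METTL1 itself differed by -0.29 (SE 0.47), its partner WDR4 by -0.24 (SE 0.43, and 0.0055 without heated replicate 1) and the transcription factor SNAI1 by 0.85 (SE 0.46), and none of them passed.

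In the Huh7 polysome libraries the heat shock genes followed the labels in replicate 1 and ran against them in replicate 2. HSPA6 stood at 1.08 FPKM in the library labelled unheated replicate 1 and at 163 in the library labelled heated replicate 1, but at 369 in the library labelled unheated replicate 2 and at 0.76 in the library labelled heated replicate 2. HSPA1A, DNAJB1 and FOS had the same arrangement, at 2139, 1084 and 39.1 FPKM in the library labelled unheated replicate 2 and at 57.7, 94.3 and 1.75 in the library labelled heated replicate 2. Of the 19 genes called in the inputs alone, 18 lay nearer the heated inputs in the library labelled unheated replicate 2, and 0 did in the library labelled heated replicate 2. The corresponding numbers were 0 and 18 in the libraries labelled unheated and heated replicate 1. Every direction that uses the Huh7 polysome libraries rests on the labels as given.

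**Figure D1:**
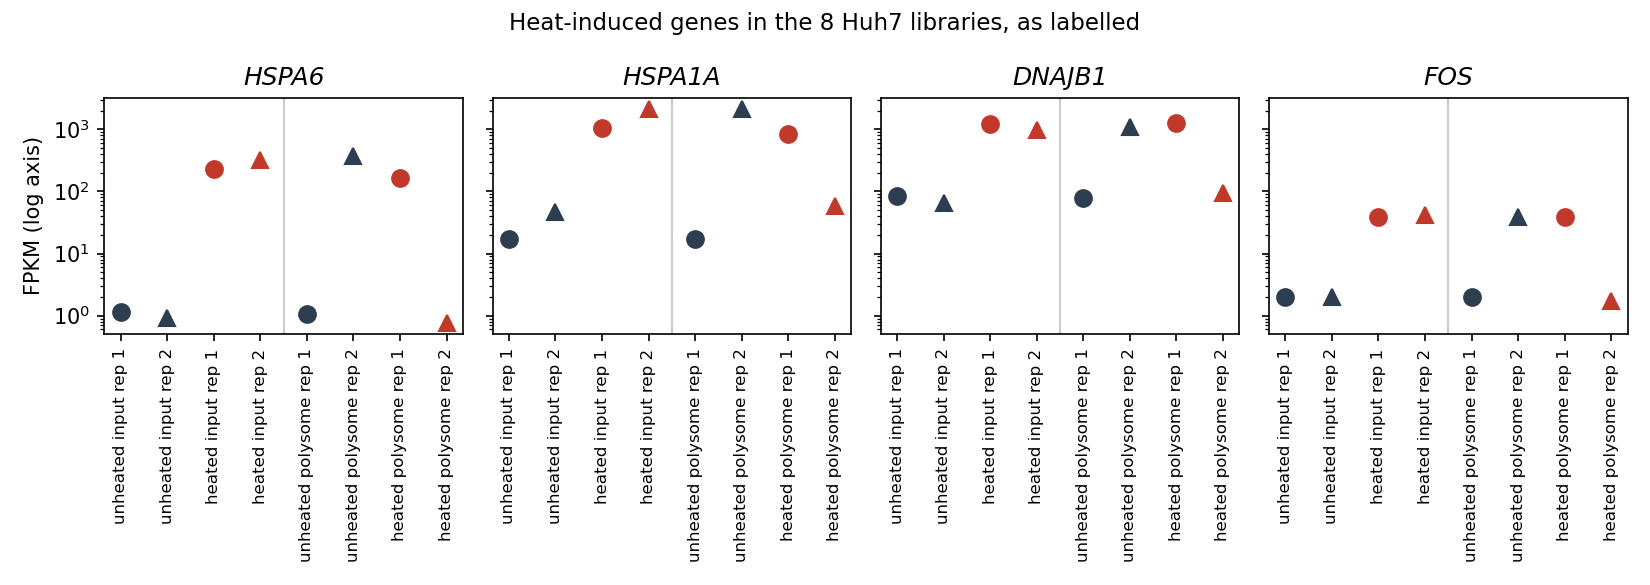
FPKM on a log axis of HSPA6, HSPA1A, DNAJB1 and FOS in each of the 8 Huh7 libraries, with 1 point per library. HSPA6 lies at 369 FPKM in the library labelled unheated polysome replicate 2 and at 0.76 FPKM in the library labelled heated polysome replicate 2.

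Heat shock genes had no common direction between the polysome libraries labelled heated and those labelled unheated. Their median log2 difference was 0.12 over both replicates, against 1.59 in replicate 1 and -1.12 in replicate 2, and that of the immediate early genes was 0.09. In this comparison, which asks which mRNAs were more engaged by ribosomes after heat, limma called 0 genes, and 0 had an unadjusted p under 0.05. Unchanged genes alone would give a share of about 0.05, so this test was too conservative to show that nothing changed. Replicate deviations of the polysome groups correlated at 0.68, and the replicate was not in the fit. The genes with the smallest p were CD72 at 0.67, TNFAIP8L2-SCNM1 at 0.73, OOEP at 0.71, HIST1H2BH at 0.69 and LOC107984314 at 0.50, and on the lower side HIST1H4K at -1.10, TVP23C-CDRT4 at -0.78, S100A3 at -0.67, PROCR at -0.45 and FAM156A at -0.52. HIST1H4K was at 0.18 without the library labelled heated replicate 1, where it was listed at 0, and TVP23C-CDRT4 at 0.060 without that labelled heated replicate 2. METTL1, WDR4 and SNAI1 differed by 0.04, 0.12 and 0.09, with signs that single libraries turned. Without the library labelled heated replicate 2, METTL1 was at -0.59 and WDR4 at -0.15, without unheated replicate 1 WDR4 was at -0.028 and SNAI1 at -0.44, and without heated replicate 1 SNAI1 was at -0.084. Camera placed 7 lists apart, led by G2/M cell cycle genes, positive in 26 of 30 (median 0.24, adjusted p = 2.81e-06, and adjusted p = 0.495 with an estimated correlation). The G2/M median was 0.42 in replicate 1 and -0.016 in replicate 2 as labelled. Without both replicate 2 polysome libraries, an alternative chosen after seeing the data, 1 gene passed in limma, HSPA6 (adjusted p = 0.0148), with a single polysome library on each side that was assumed to vary like the inputs. METTL1, WDR4 and SNAI1 were then at -0.55, -0.0035 and 0.80.

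The change of the Huh7 polysome-to-input ratio with heat, tested as an interaction, asks whether ribosome association moved beyond mRNA level, and for heat shock genes the replicates differed as labelled. Their median heat difference in replicate 1 was 1.59 in polysomes and 1.28 in input, and in replicate 2 it was -1.12 and 1.20. For ribosomal protein genes these medians were -0.11 and 0.0043 in replicate 1 and 0.058 and -0.58 in replicate 2. Values over both replicates therefore rest on replicate 2 for both lists. HSPA6 had an interaction of -7.77 (SE 3.18), PLCG2, a phospholipase, of -2.57 (SE 0.71), U2AF1L5 of -2.40 and FOXE3 of -1.23, while LOC101928093, also among the smallest p, was listed at 0 in both unheated inputs. On the positive side the smallest p belonged to SMIM11A at 1.84, CYP2D7 at 1.10, PSKH1 at 1.11, GEMIN6 at 1.64 and RPP14 at 0.95. No gene passed in limma (0 calls, with 7 at an unadjusted p under 0.05). That is far fewer than the share of about 0.05 that unchanged genes would give, so this test was conservative as well. Heat shock genes were negative in 37 of 39 (median -1.12, camera adjusted p = 3.19e-48, and adjusted p = 0.146 with an estimated correlation), and ribosomal protein genes positive in 73 of 79 (median 0.26, adjusted p = 7.65e-09, and adjusted p = 0.379 with an estimated correlation). Without both replicate 2 polysome libraries, the interaction of HSPA6 was -0.76 and that of PLCG2 -1.45, with FOXE3 at -0.67, PSKH1 at 0.37, GEMIN6 at 0.20 and RPP14 at 0.37. In that fit, chosen after seeing the data, the heat shock median was 0.10 with adjusted p = 0.273, the ribosomal protein median was 0.16 with adjusted p = 2.18e-05 while both replicate 2 inputs stayed in, and the number of lists placed apart went from 12 to 2. METTL1, WDR4 and SNAI1 had interactions of 0.33, 0.36 and -0.76, and of -0.26, 0.24 and -0.049 in that fit, and METTL1 was at -0.30 without the library labelled heated polysome replicate 2 alone.

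Ferritin and ribosomal protein mRNAs were lower in polysomes than in input of Huh7 cells labelled unheated, a comparison that shows what the fraction holds. FTL, the ferritin light chain whose mRNA carries an iron-responsive element, had 27049 and 11861 FPKM in input and 2016 and 2127 in polysomes, a log2 difference of -3.11 (SE 0.49, adjusted p = 0.982 in limma). The next smallest p belonged to FTH1, the heavy chain, at -2.92, RPLP1 at -1.93, RPS29 at -1.54 and CYP2D7 at -1.42, and both ferritin genes have pseudogenes that can share reads. Among genes higher in polysomes it belonged to LOC101928589 at 1.52, LOC102723728 at 1.33, LOC107987423 at 2.25, CACYBP at 1.38 and LDLRAD2 at 2.27. No gene passed in limma (0 calls, 50 at an unadjusted p under 0.05, fewer than the share of about 0.05 that unchanged genes would give). METTL1, WDR4 and SNAI1 differed by -0.27, -0.05 and 0.15. WDR4 was at 0.16 without unheated input replicate 2 and at 0.10 without the library labelled unheated polysome replicate 1, and SNAI1 at -0.38 without that labelled unheated polysome replicate 2. Camera placed 8 lists apart, and 0 with an estimated correlation. Among them, heat shock genes were positive in 38 of 39 (median 0.93, adjusted p = 3.15e-18, and adjusted p = 0.424 with an estimated correlation), and without both replicate 2 polysome libraries the adjusted p was 0.549. Of 79 ribosomal protein genes, 72 were negative (median -0.51, 2 lower when adjusted over the list alone), among them RPSA at -1.63, with adjusted p = 8.33e-48 and adjusted p = 0.235 with an estimated correlation. All 35 proteasome and ubiquitin genes were positive (median 0.38), including PSMD12 at 0.81 and PSMD14 at 0.73, with adjusted p = 1.56e-06 and adjusted p = 0.143 with an estimated correlation, and adjusted p = 0.338 without both replicate 2 polysome libraries.

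METTL1 mRNA was lower in both SNU449 knockdown libraries than in any other library of that line. It stood at 26.6, 26.9 and 6.10 FPKM in the input of NC unheated, NC heated and knockdown heated cells and at 32.8, 22.8 and 5.54 FPKM in their polysomes, so the knockdown retained 22.7% and 24.3% of the NC heated level. WDR4 stood at 22.8, 7.52 and 23.6 FPKM in the inputs and at 29.2, 18.1 and 23.7 in the polysomes. SNAI1, a driver of epithelial-mesenchymal transition, stood at 1.26, 6.89 and 21.4 FPKM in the inputs and at 1.11, 28.0 and 10.1 in the polysomes, while SNAI2 stayed under 1 FPKM in all 6. With 1 library per group, the SNU449 differences have no replicate error and no p-value.

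Heated SNU449 cells held far more heat shock mRNA in both fractions, and more immediate early mRNA in polysomes, than unheated cells. HSPA6 went from 3.27 to 667 FPKM in input and from 1.17 to 2811 FPKM in polysomes. In input the next largest log2 increases were RGS2 at 4.98, HSPA1B at 4.33, FOSB at 4.33, CRYAB at 4.20, ARC at 4.04, ID2 at 3.94, EGR1 at 3.91, HSPA1A at 3.69 and ANKRD1 at 3.58. In polysomes they were FOSB at 6.63, HSPA1B at 6.55, EGR1 at 6.34, ARC at 6.18, FOS at 6.14, HSPA1A at 6.06, CRYAB at 4.64, DNAJB1 at 4.29 and RGS2 at 4.12. The largest input decreases were NUAK2 at -3.03, FJX1 at -2.93, LIF, a cytokine, at -2.71, IRF1 at -2.52, PDGFB at -2.50, GLIS2 at -2.49, PPRC1 at -2.48, NFKBIA at -2.45, SKI at -2.45 and BMF at -2.42. The largest polysome decreases were ALDH3A1 at -2.37, CCDC71 at -2.31, HPS6 at -2.29, EFNA4 at -2.21, INTS5 at -2.16, TMEM121 at -1.90, TMEM177 at -1.89, FJX1 at -1.86, ELF3 at -1.85 and SPC24 at -1.85. The heat shock list had medians of 1.42 in input and 1.13 in polysomes, each at percentile 100 of 10000 random lists matched on expression. Such percentiles are not p-values, since genes of a list can move together and the spread between libraries is not in them.

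By count, 3479 of 9894 genes differed by at least 1 (log2) in heated SNU449 input, 1322 higher and 2157 lower, and 568 in polysomes, 181 higher and 387 lower. With a pseudocount of 0.1, an alternative added after seeing the data for polysomes, the polysome count was 927. Median-of-ratios scaling moved the median of all genes in input from -0.23 to -0.03 and the share of higher genes from 38.0% to 60.3%, with 1893 higher and 1248 lower. Ribosomal protein genes had medians of 0.95 in input (1.19 scaled) and -0.39 in polysomes (-0.35 scaled), the latter at percentile 0.01. Immediate early genes had a median of 1.13 in polysomes and -0.33 in input, at percentiles 100 and 56.1. Across genes, which are not independent replicates, the NC heated input library correlated at 0.852 to 0.900 with the other SNU449 libraries.

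The polysome-to-input ratio of heated against unheated NC cells was higher for immediate early, mesenchymal and other lists and lower for ribosomal protein and other lists. The largest log2 increases were HSPA6 at 3.05, FOS at 2.59, MAP4, a microtubule protein, at 2.52, EGR1 at 2.43, MYH9, a non-muscle myosin, at 2.38, HSPA1A at 2.37, FOSB at 2.30, EIF3C at 2.26, ACTN4 at 2.25 and NFIX at 2.24. The largest decreases were RPS12 at -2.86, RPL12 at -2.34, LRRC75A at -2.32, RPS20 at -2.29, RPLP1 at -2.19, ALDH3A1 at -2.07, LOC105371063 at -2.02, RPL41 at -2.002 and RPL30 at -2.001, while BGLAP, also among them, was listed at 0 in the unheated input. By at least 1, 1306 genes were higher and 617 lower. In simulated data, with 1 spread taken from the unheated Huh7 inputs, 7.5% of unchanged genes reached 1 in the ratio and 1.3% in polysomes. Counts of the ratio and of polysomes therefore cannot be set side by side, and the noise of these SNU449 libraries is unknown. Scaling moved the median of all genes from 0.10 to -0.08 and the share of higher genes from 67.9% to 42.4%. Immediate early genes had a median of 1.42 (1.25 scaled, percentile 100), mesenchymal genes of 0.85 (0.64 scaled, percentile 99.94) and ribosomal protein genes of -1.30 (-1.51 scaled, percentile 0). Other lists lay about as far out. Integrated stress response genes had 0.86 (0.65 scaled, percentile 99.96) and glycolysis and hypoxia genes 0.58 (0.37 scaled, percentile 99.68). Oxidative phosphorylation genes had -0.69 (-0.90 scaled, percentile 0.01) and replication-dependent histone genes -0.49 (-0.56 scaled, percentile 0.02). The ratio uses the NC heated input library, which correlated at 0.852 to 0.900 with the other libraries. With the polysomes of the same cells it correlated at 0.900, where the NC unheated and knockdown pairs were at 0.979 and 0.981. The heat medians of the immediate early, mesenchymal and ribosomal protein lists were -0.33, -0.39 and 0.95 in input and 1.13, 0.35 and -0.39 in polysomes.

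Knockdown of METTL1 in heated SNU449 cells went with more LCN2 and SAA1 mRNA in both fractions and with less immediate early mRNA in polysomes, where that list had a median of -0.96 (-0.70 scaled, percentile 0.440), against 0.55 (0.70 scaled, percentile 98.9) in input. In input, LCN2, a secreted protein of inflammation, was listed at 0 in the NC heated library and stood at 31.2 FPKM in the knockdown library. SAA1 and C3, of the same kind, differed by 4.33 and 4.11 (log2), followed by ANGPTL4 at 3.98, LOC101928120 at 3.55, RRAD at 3.47, OLFM2 at 3.26, TMEM88 at 3.21, CDC42EP2 at 3.19 and LTB at 3.16. Lower in input were CHTF8, listed at 0 in the knockdown library against 18.4 FPKM, and PYURF at -4.05, MRPL13 at -3.68, CLTRN at -3.60, PBK at -3.56, ATP5PB at -3.50, MPHOSPH6 at -3.49, ANAPC13 at -3.45, TM2D1 at -3.42 and MAD2L1 at -3.39. In polysomes the largest increases were LCN2 at 5.38, PLD4 at 4.95, SAA1 at 4.89, INHBA at 4.42, LOC101928120 at 4.13, ALDH3A1 at 4.06, KTN1 at 3.75, NSRP1 at 3.65 and BGLAP at 3.55, with LYL1 listed at 0 in NC heated polysomes. FOS went from 130.5 to 4.62 FPKM and EGR1 from 399 to 23.5 FPKM in polysomes, beside RAB32 at -4.37, PPP2R5D at -4.30, GEMIN7 at -3.70 and KLF10 at -3.67, while CHTF8, ABCF2-H2BE1, PYURF and TMEM189-UBE2V1 were listed at 0 in knockdown polysomes.

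At least 1 log2 unit separated knockdown from NC heated cells for 3284 genes in input (1032 higher) and 3146 in polysomes (828 higher). Scaling moved the median of all genes from -0.09 to 0.06 in input and from -0.40 to -0.13 in polysomes, and the share of higher genes from 31.4% to 44.2% and from 26.3% to 45.4%. In input, p53 targets had a median of 0.96 (1.14 scaled, percentile 99.99), NF-kB targets of 0.84 (1.03 scaled, percentile 100) and G2/M genes of -1.14 (-0.95 scaled, percentile 0). These rest on the NC heated input library, whose same lists stood at -0.78, -0.49 and 0.49 against the unheated input, and in polysomes the knockdown medians were -0.23, -0.036 and -0.42 (0.076, 0.27 and -0.088 scaled). In polysomes, ribosomal protein genes had a median of 1.64 (2.004 scaled, percentile 100), replication-dependent histone genes of 1.03 (1.35 scaled, percentile 100) and mesenchymal genes of -1.26 (-0.91 scaled, percentile 0). The knockdown polysome library itself correlated across genes at 0.852 to 0.907 with the 4 NC libraries and at 0.981 with the knockdown input. It listed 8882 genes at 1 FPKM or more, where the other SNU449 libraries listed 9224 to 10413. In input these 3 lists had medians of opposite sign, at -0.33, -0.30 and 0.31 (-0.14, -0.19 and 0.51 scaled).

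With knockdown the polysome-to-input ratio was lower for immediate early and other lists and higher for ribosomal protein and other lists. The largest log2 decreases were DLX2 at -3.73, DUSP1, a MAP kinase phosphatase, at -3.62, MYC at -3.50, BCAR3 at -3.20, BAG3 at -3.15, FOS at -3.15, IER5 at -3.07, AMOTL2 at -3.01, CCN2 at -2.98 and GLB1 at -2.96. The largest increases were KTN1 at 4.67, NSRP1 at 4.03, MTRNR2L6 at 3.93, MTRNR2L1 at 3.86, MTRNR2L10 at 3.78, LARP7 at 3.70, LUC7L3 at 3.47, NOP58 at 3.42, HSP90AA1 at 3.41 and SLU7 at 3.37, and the MTRNR2L genes are near-identical copies that can share reads. Counting both ways, 1433 genes were higher and 2269 lower by at least 1, and scaling moved the median of all genes from -0.26 to -0.12 and the share of higher genes from 38.7% to 49.2%. Immediate early genes had a median of -1.94 (-1.80 scaled, percentile 0), mesenchymal genes of -1.44 (-1.27 scaled, percentile 0) and ribosomal protein genes of 1.90 (2.07 scaled, percentile 100). Other lists had percentiles as far out, with glycolysis and hypoxia genes at -1.25 (-1.09 scaled, percentile 0). Replication-dependent histone genes had 1.21 (1.37 scaled), G2/M genes 0.79 (0.93 scaled) and oxidative phosphorylation genes 0.61 (0.78 scaled), each at percentile 100. The knockdown ratio uses the knockdown polysome library, which correlated at 0.852 to 0.907 with the NC libraries. The heat and knockdown ratios both use the NC heated libraries, so part of their opposite directions follows from the shared libraries.

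**Figure D2:**
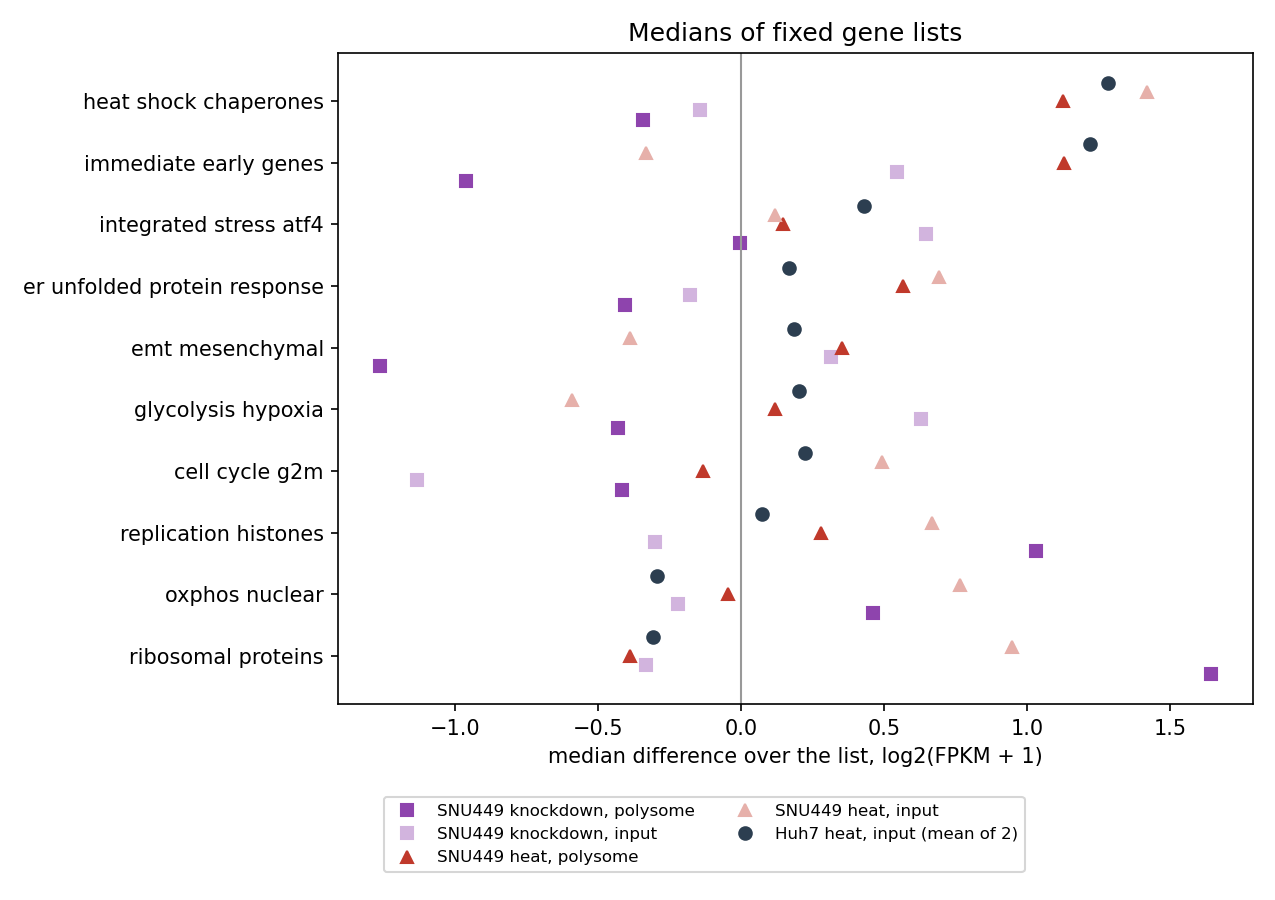
Median difference in log2(FPKM + 1) over the members of 10 fixed gene lists, with 1 point per list and comparison, for heat in Huh7 input, heat in SNU449 input and polysomes, and METTL1 knockdown in heated SNU449 input and polysomes, values as deposited. The heat shock list lies at 1.28, 1.42 and 1.13 in the heat comparisons, and the ribosomal protein list at 1.64 in knockdown polysomes.

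HSPA6, HSPA1B, FOSB, EGR1 and CRYAB were higher in heated input in both Huh7 and SNU449, while across all genes the input changes of these lines were nearly uncorrelated. Over 9054 genes, Pearson's r across genes was 0.04 for input, -0.18 for polysomes and -0.16 for the ratio, with Spearman's rho of -0.06, -0.25 and -0.13. With replicate 1 alone for the Huh7 polysomes, chosen after seeing the data, r was 0.36 and rho 0.17. The Huh7 input change correlated with the SNU449 polysome change at r = 0.48 (rho 0.32), also chosen after seeing the data, and the SNU449 input change uses the NC heated input library, which correlated at 0.852 to 0.900 with the others of that line.

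The initiator methionine tRNA iMet-CAT and the isoleucine tRNA Ile-TAT had the highest NaBH4-to-input read ratios in MHCC97H, and in summed reads the ratio increased most with heat for Pro tRNAs and decreased most for Lys tRNAs. The libraries were made to map m7G on tRNA with and without heat. This ratio sums reads over fragments and uses no cleavage positions, so it is not a measure of m7G level. Without heat the ratio was 20.4-fold for iMet-CAT, 15.5-fold for Ile-TAT, 7.85-fold for Tyr-GTA, 7.11-fold for Asn-GTT and 6.12-fold for Ala-AGC. Scaled to total reads, an alternative added after seeing the data, the first 3 became 11.1-fold, 8.73-fold and 4.29-fold. The heated minus unheated log2 ratio was highest for Pro-TGG at 0.77, Pro-AGG at 0.73, Pro-CGG at 0.64, Asp-GTC at 0.58 and Val-AAC at 0.51, and lowest for Lys-TTT at -0.49, Lys-CTT at -0.42, Phe-GAA at -0.40, Ile-AAT at -0.25 and Ile-TAT at -0.21. With 3′ or with 5′ fragments alone, chosen after seeing the data, the Pro-AGG change was -0.073 or -0.036, and it was -0.12 over feature medians. Asp-GTC turned to -0.31 over feature medians and to -0.23 with 5′ fragments alone, and Ile-AAT to 0.43 with 5′ fragments alone. Of 47 anticodons kept out of 49, 32 were higher and 15 lower, with a median of 0.12. Over feature medians 18 were higher and 29 lower (median -0.029), and scaled to total reads, added after seeing the data, 15 and 32 (median -0.16). Ratios with and without heat correlated at 0.97 across anticodons, which are not independent replicates. No count test was run, because each group had 1 library. The largest standard error of a change, 0.0368, covers counting only and takes each read as counted once.

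**Figure D3:**
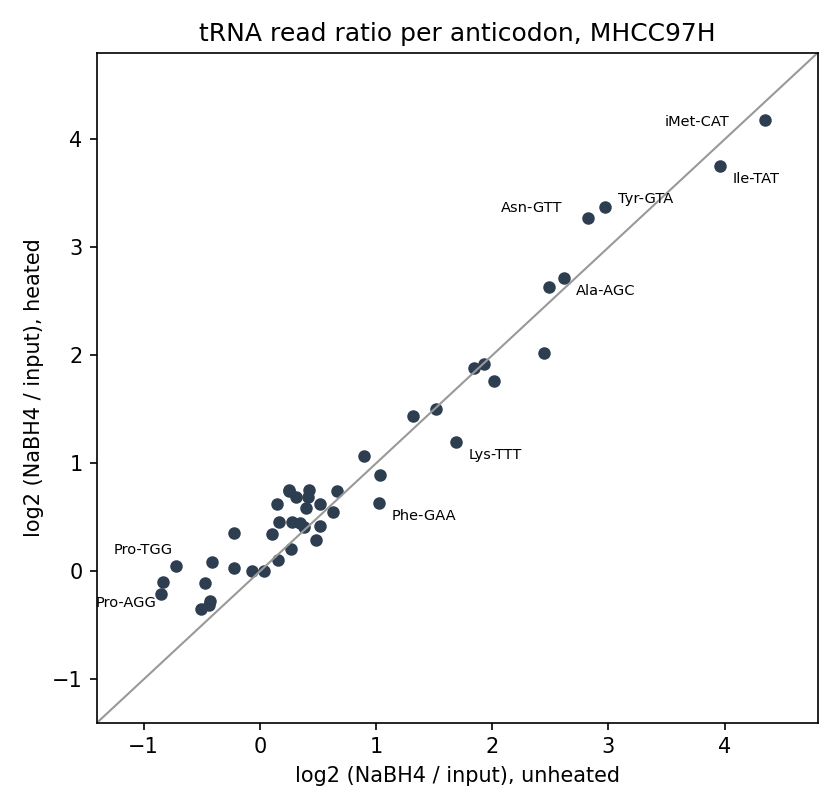
Log2 ratio of NaBH4-treated to input reads in heated against unheated MHCC97H cells, 1 point per anticodon, with the line of equal values. Unheated ratios run to 4.35 for iMet-CAT, and Pro-TGG lies 0.77 above the line.

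In summed reads, Thr tRNAs were higher and Pro tRNAs lower in the heated than in the unheated MHCC97H input library. The largest log2 increases were Thr-TGT at 1.34, Thr-CGT at 1.26, Thr-AGT at 1.10, Lys-CTT at 1.10 and Phe-GAA at 1.09, and the largest decreases Pro-AGG at -1.56, Pro-CGG at -1.46, Pro-TGG at -1.36, Gly-GCC at -0.98 and Gly-CCC at -0.84. The Pro and Gly differences had the opposite sign with 3′ fragments alone, an alternative chosen after seeing the data, at 0.56 for Pro-AGG and 0.12 for Gly-GCC, and over feature medians, at 1.10 and 0.21. Thr-AGT had the opposite sign with 5′ fragments alone, at -3.64. A 5′ feature of Gly-GCC and one of Gly-CCC had 144337 and 139823 reads in the unheated and 143090 and 134487 in the heated input. The largest 5′ features of the Pro anticodons had 111434 to 113450 reads in the unheated input. The same reads were likely counted for both Gly anticodons, and likewise for the Pro anticodons, so differences within each amino acid are likely not independent. The median over 47 anticodons was 0.34, with 36 higher and 11 lower, and median-of-ratios scaling turned it to -0.38, with 13 higher and 34 lower. Over feature medians it was 0.77, with 46 higher and 1 lower, and with 3′ or 5′ fragments alone it was 0.52 or 0.21. The share of 3′ fragments among mature tRNA reads of Pro-AGG was 7.32% (95% Wilson interval 7.22 to 7.42) without heat and 32.0% (31.8 to 32.2) with heat, and that of Gln-TTG was 61.4% (61.0 to 61.8) and 97.0% (96.9 to 97.0). With intervals apart, this share was larger with heat for 34 anticodons and smaller for 11. Such intervals cover counting error only, and are too narrow even for that where near-identical features counted the same reads.

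**Figure D4:**
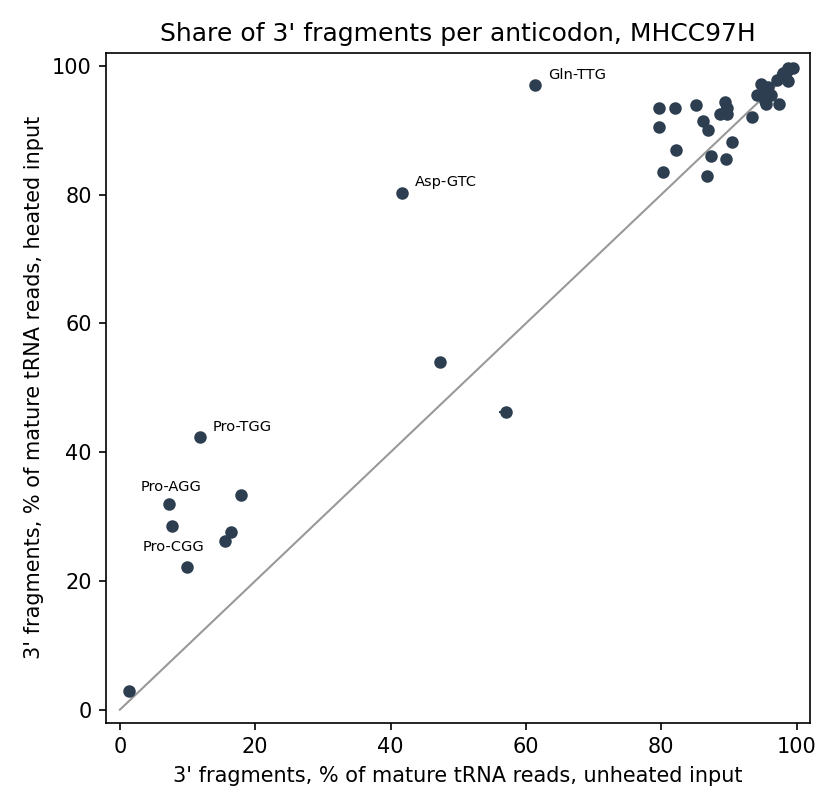
Share of 3′ fragments among mature tRNA reads, in percent, in the heated against the unheated input library of MHCC97H, 1 point per anticodon with 95% Wilson intervals and the line of equal shares. Pro-AGG moves from 7.32% to 32.0%, and 11 anticodons lie below the line with intervals apart.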

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

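All tests of explanations here were chosen after the result was seen.

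Heat-induced genes such as HSPA6 ran against the labels in both Huh7 polysome libraries of replicate 2. Of 19 genes called in the inputs, 18 were out of place in both of these libraries, which is what exchanged labels would give. The reversal held across all genes. The polysome change correlated with the input changes of replicates 1 and 2 at -0.62 and -0.64 in replicate 2, and at 0.85 and 0.59 in replicate 1. With heated and unheated input replicate 2, the library labelled unheated correlated at 0.989 and 0.974, and that labelled heated at 0.972 and 0.979. A single wrong or mixed library would leave most genes in place in the other, and at most 1 of the 19 lay nearer the inputs of its own label. An opposite response to heat in the polysomes of replicate 2 may give such values (median log2 difference of 3.42 between the library labelled unheated and the unheated inputs), but would need mRNA far above its own input, 406-fold for HSPA6 and a median of 15.2-fold over 18 of these genes, where replicate 1 had 0.947-fold and 0.869-fold. These values go against it without excluding it, since the share of mRNA in polysomes was not measured.

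In SNU449, the ratio changes of genes such as FOS and RPS12 with heat and with METTL1 knockdown ran opposite ways, with r = -0.79 across genes. Both use the NC heated libraries, and simulated unchanged libraries that share them gave -0.50, which equal noise gives in any such design. The simulated noise was taken from the Huh7 input replicates, another cell line without polysomes. The covariance was -0.63 against -0.33 simulated, but the noise of unrepeated libraries is unknown. With the polysome libraries alone r was -0.18 (covariance -0.10) against a simulated -0.50 (-0.16). A much weaker r is what an NC heated input library standing apart would give. It does not single out that cause, since polysome changes also hold changes of mRNA level. Knockdown turning back the heat change cannot be told apart from these, since these libraries hold no repeat of a heated SNU449 library and no unheated knockdown.

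In MHCC97H, the 3′ share of Pro tRNA reads was larger in the heated input library, by 24.7 percentage points for Pro-AGG. The whole input library went from 58.9% to 77.7% 3′ reads, with a larger share for 34 anticodons and a smaller one for 11, so a shift of the library may account for part of this and is not excluded. In the feature of each of the 3 Pro anticodons with the most 5′ reads, their numbers differed by a factor of 1.02 (111434, 113173 and 113450 in the unheated input). The same reads were therefore likely counted for all of them, and these are likely 1 pattern and not 3. An effect of heat cannot be told apart from a difference between single libraries.

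Some gene lists had medians of opposite sign in both Huh7 input replicates and in the SNU449 input library, where the median of all genes was -0.23, and the difference was not tested. Immediate early genes had a median of -0.33 in SNU449 (percentile 56.1 of matched random lists) against 1.11 and 1.37 in Huh7, and oxidative phosphorylation genes 0.76 (percentile 99.97) against -0.20 and -0.33. SNU449 medians were -0.39 for mesenchymal genes, -0.43 for epithelial junction genes, -0.44 for hepatocyte genes and -0.59 for glycolysis and hypoxia genes, which were all positive in Huh7. Their SNU449 percentiles were 39.7, 32.3, 35.3 and 9.56, so none of these 4 lists stood apart from random lists in SNU449. G1/S genes had -0.089, which scaling turned to 0.14. METTL1 differed by 0.016 in SNU449 and by -0.29 and -0.29 in Huh7.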

How the results depend on the processing

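Called genes: heated Huh7 input went from 0 to 1 with scaling, 19 with the inputs alone, and there 532 with a replicate block (the numbers only are shared, and replicate deviations of the input groups correlated at 0.71), 21 with a pseudocount of 0.1 and 18 scaled. Leaving out 1 library gave 0 calls in the fit of all groups, except 2 and 3 without unheated polysome replicate 1 or 2, and 22 to 126 in the inputs alone, with 43 and 126 without unheated input replicate 1 or 2 and 46 and 22 without heated input replicate 1 or 2, where the lone library is assumed to vary like the others. For the ratio it gave 0 to 2 (2 without unheated polysome replicate 1). Without both replicate 2 polysome libraries, added after seeing the data, the calls were 18 for input and 1 for polysomes. In lists, estimated correlation left 0 in all 4 comparisons, leave-one-out ranged over 7 to 13 for input, 2 to 12 for polysomes, 5 to 15 for the ratio and 4 to 15 for unheated polysome against input, and without both replicate 2 polysome libraries the last 2 had 2 and 3. All polysome against all input gave 0 unfiltered, 2 scaled, 2 with a replicate block and 0 to 3 leaving out 1. SNU449 heated polysomes gave 927 with a pseudocount of 0.1. The tRNA ratio median was -0.029 over feature medians, -0.086 with 5′ fragments and -0.16 scaled to total reads, and the level median -0.38 with median-of-ratios scaling, 0.77 over feature medians, 0.52 with 3′ fragments, 0.21 with 5′ fragments and 0.23 scaled to total reads. Opposite signs were seen for the following (leave-one-out as ranges). In Huh7 input, WDR4 ranged from -0.48 to 0.0055. In Huh7 polysomes, HIST1H4K ranged from -2.38 to 0.18, TVP23C-CDRT4 ranged from -1.62 to 0.060, METTL1 ranged from -0.59 to 0.67 and was -0.00040 scaled and was -0.55 without both replicate 2 polysome libraries, WDR4 ranged from -0.15 to 0.39 and was -0.0035 without both replicate 2 polysome libraries, SNAI1 ranged from -0.44 to 0.62. In the Huh7 ratio, METTL1 ranged from -0.30 to 0.96 and was -0.26 without both replicate 2 polysome libraries. In unheated Huh7 polysome against input, WDR4 ranged from -0.25 to 0.16, SNAI1 ranged from -0.38 to 0.68 and was -0.38 without both replicate 2 polysome libraries. For the tRNA ratio with feature medians, Pro-TGG was -0.081, Pro-AGG was -0.12, Pro-CGG was -0.0079, Asp-GTC was -0.31. For the tRNA ratio with 3′ fragments, Pro-TGG was -0.0049, Pro-AGG was -0.073. For the tRNA ratio with 5′ fragments, Pro-TGG was -0.085, Pro-AGG was -0.036, Pro-CGG was -0.086, Asp-GTC was -0.23, Ile-AAT was 0.43. For the tRNA level with feature medians, Pro-AGG was 1.10, Pro-CGG was 0.65, Pro-TGG was 0.66, Gly-GCC was 0.21, Gly-CCC was 0.97. For the tRNA level with 3′ fragments, Pro-AGG was 0.56, Pro-CGG was 0.43, Pro-TGG was 0.46, Gly-GCC was 0.12, Gly-CCC was 0.32. For the tRNA level with 5′ fragments, Thr-AGT was -3.64. For all of these the cause was not tested. The cross-line correlations moved by less than a tolerance set by how far the Huh7 replicates differed. For polysomes these replicates ran opposite ways, so that tolerance is too wide to show stability. With Huh7 polysome replicate 1 alone, r turned from -0.18 to 0.36. The other SNU449 counts stayed within 1.5 times. FPKM gives no depth, so no limit from depth can be given for the mRNA libraries.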

Other observations

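All comparisons here were chosen after the data were seen. FTL, the ferritin light chain, and ribosomal protein genes were lower in polysomes than in input when all 4 polysome libraries of Huh7 were set against all 4 input libraries, which does not use the heat labels. FTL had a mean of 17458 FPKM in input (SD 8509, n = 4) and 2188 in polysomes (SD 164, n = 4), and in limma it fell (log2 -2.86, SE 0.32, adjusted p = 0.0246), lower in 4 of 4 polysome libraries. The call was lost without the FPKM minimum and without any 1 library other than heated input replicate 2 or unheated polysome replicate 1 (log2 -2.60 to -3.14 leaving out 1, adjusted p = 0.00265 to 0.195 over all alternatives). It was the 1 gene called, with its libraries separated, which chance gives 2.86% of genes, and 216 genes had an unadjusted p under 0.05. Unchanged genes would give more, a share of about 0.05, so this test was conservative. Ribosomal protein genes had a median of -0.36 (-0.49 scaled, 8 lower when adjusted over the list alone), with camera adjusted p = 1.18e-45 and adjusted p = 0.161 with an estimated correlation. The median of all genes was 0.14, or 0.03 scaled. Of 35 splits of the 8 libraries, 4, the real one among them, called at least as many genes as the real value of 1. The highest, 1828, was replicate 1 against replicate 2. Setting replicate 1 inputs and replicate 2 polysomes against the rest gave 458. Setting the unheated inputs, the library labelled unheated polysome replicate 1 and that labelled heated polysome replicate 2 against the rest gave 54. These follow a structure of the samples, so the count cannot measure chance, which is not excluded in this fit without the replicate. With a replicate block, FTL and FTH1 were called (2 genes).

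A hypothesis was that Leu, Ser and SeC tRNAs, which have a long variable arm where other tRNAs can carry m7G, may have a lower NaBH4-to-input ratio in unheated MHCC97H cells. The mean log2 ratio was 0.44 (SD 0.26) over 10 such anticodons and 0.87 (SD 1.36) over 37 others. The difference was -0.43 (two-sided permutation test with 100000 resamples, p = 0.329). The test took the anticodons of a single pair of libraries as independent, although near-identical tRNAs can share reads, and the groups differed in spread. The ratio is also not a measure of m7G level, so the test cannot decide and the hypothesis stays open.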
